A study of Mus musculus with 9 samples.

How the data were processed

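The series holds 9 ATAC-seq libraries of differentiated C2C12 myotubes, prepared by the Omni-ATAC protocol per the labels' protocols, in 3 groups of 3: untreated, 10 mM ammonium acetate for 3 h, and 10 mM for 24 h. Groups were taken from the labels. Per the submitters' processing notes, the tools were FastQC, Trim Galore 0.4.5 with cutadapt 1.15, Bowtie2 2.3.4.1, Picard 2.20.2, SAMtools, bedtools, MACS2, MultiQC and edgeR, with the genome build mm10. The order and settings of these steps, any shift of reads for the transposase, and whether peaks were called per library or on pooled libraries are not given in the sources used here.

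The authors deposited 1 table per comparison, with 1 line per region and annotation, and these were collapsed to 588, 150 and 1256 regions for 3 h against untreated, 24 h against untreated and 24 h against 3 h. The authors' log2 fold change and mean log2 CPM per region were used as deposited. The p-value and the Benjamini-Hochberg adjusted p-value of each region are those the authors deposited. The F statistic deposited by the authors is a score without a fixed range, and with the p-value it gives 21.5 denominator degrees of freedom for every region. Per the file headers, the annotation classes are promoters, sequence 1 to 5 kb upstream, untranslated regions, exons, introns, intergenic sequence and CpG islands, shores and shelves. The tables hold only regions past a threshold, and the threshold differed: by their values, raw p below 0.005 with at least a 1.5-fold change for 3 h against untreated and 24 h against 3 h, and adjusted p below 0.05 for 24 h against untreated. The lists are therefore not comparable in length. A common limit for the 3 lists, the largest raw p of the 24 h list, was added after seeing the data.

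From the adjusted p and its rank, 146047 tested regions were recovered. The same relation bounds the number of regions at or below the largest p of each list. An approximate standard error was taken as the absolute log2 fold change over the square root of F, with medians of 0.21, 0.20 and 0.22 in the 3 comparisons. Because the tables hold no columns per library, depth per library is unknown, and no test across libraries, no blocked fit, no omission of a replicate and no regrouping of libraries could be run. A missing log2 fold change was derived from the other comparisons on the assumption that the 3 add up, which held in the 3 regions present in all lists and could not be checked in any other.

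Shares of regions carry 95% Clopper-Pearson intervals. Higher and lower regions were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, and log2 odds ratios were computed with 0.5 added to each cell. Medians and means were compared by two-sided permutation tests with 100000 resamples. Gene names were taken from the tables, where 1050 of 1052 gene identifiers matched the RefSeq table of the same assembly (GRCm38). Genes within 5 kb of a region were taken from that table after seeing that most intergenic regions carried no gene. A region in the flank of a gene lies within 5 kb of it, outside its body, with no promoter or upstream annotation. Gene density is the number of protein-coding genes whose midpoint lies in a 500 kb window centred on the region.

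Choices made before the data were examined were the 17 gene lists, the annotation and overlap tests, the alternatives, and the rule for named genes: per comparison and direction the 8 regions with the smallest adjusted p at a named gene, the 3 with the largest fold, and up to 4 members of each list. The gene lists covered ammonia and amino acid metabolism, the integrated stress response, NF-kB, hypoxia and glycolysis, mitochondrial metabolism, insulin and mTORC1 signalling, atrophy, sarcomere, myogenic regulators, AP-1 and immediate early genes, oxidative stress, p53 and cell cycle, TGF-beta and YAP, ion transport, and markers of fibroblasts, myoblasts and adipocyte or smooth muscle cells. Tests of 28 sequence motifs were planned but not run, since no genome sequence was used here. Some members of the gene lists and some genes that the rule names are not reported here. A planned correlation of fold changes between lists was left out because both lists are truncated on the values correlated.

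To give the overlap expected with no effect, group means of 3 libraries were drawn for 146047 regions with the authors' degrees of freedom in 100 runs, and the lists' p limits were applied without their fold limits. On simulated data with 200 changed regions, the recovery of the number tested held in 20 of 20 runs, as did the bound on the number of regions. Both follow from the Benjamini-Hochberg formula, so these runs check the computation only. Fisher's exact test called 100% of 2000 simulated differences, all of a single large size, and 5.15% of 2000 simulations without one. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.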

Results

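Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in C2C12 myotubes, multinucleate muscle cells differentiated from a mouse myoblast line. The series examined how such myotubes respond to excess ammonia. Cultures were left untreated or were given 10 mM ammonium acetate for 3 h or for 24 h, with 3 libraries in each of the 3 groups and 9 libraries in all. No time is given for the untreated group, and the same untreated libraries are the control at 3 h and at 24 h. Time in culture may therefore differ between groups along with exposure, and their effects cannot be told apart here. The labels describe the libraries of a group as biological replicates. No group received acetate without ammonium, so an effect of ammonia cannot be told apart from an effect of acetate. The material analysed here was the authors' list of regions for each of 3 comparisons: 3 h against untreated, 24 h against untreated, and 24 h against 3 h. The lists hold no values per library, so the depth of each library is unknown here, and the spread between replicates enters only through the authors' edgeR test. Regions are called higher or lower by the sign of the listed log2 fold change, whether or not they passed the adjusted threshold. All coordinates are on mm10. Regions and genes are not independent replicates, and the intervals on shares of regions cover counting error only.

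After 3 h, accessibility rose 4.05-fold at a region 2621 bp from Klf2 (chromosome 8, 72324275 to 72325110, intergenic), a zinc finger transcription factor gene (log2 fold change 2.02, edgeR adjusted p = 0.00976 in the authors' deposited table). This was the 1 region of the 588 listed at 3 h with an adjusted p below 0.05. The regions with the next smallest p, at Jund, Btg2 and Fos, also lay beside immediate early genes, which cells transcribe within minutes of a stimulus. In the authors' deposited table the log2 fold change was 1.91 at a region in an Iqcn intron 3305 bp from Jund (edgeR adjusted p = 0.0644), and 1.39 and 1.76 at regions 1262 and 2065 bp from Fos (0.117 and 0.119). A region 17 bp from Btg2 was 2.82-fold higher in the authors' deposited table (edgeR adjusted p = 0.117). Next by p in the authors' deposited table were regions at Neat1 (log2 fold change 1.13), Tgif1 (-0.99), H3f3b (1.04 and 1.22) and Rara (1.14), with edgeR adjusted p from 0.289 to 0.338. A region 2723 bp from Egr1 had a log2 fold change of 1.48, and a region 1427 bp from Junb one of 1.04, in the authors' deposited table (edgeR adjusted p = 0.345 and 0.338).

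Of the 34 genes on the list of AP-1 and immediate early genes, 12 had a region listed at 3 h within 5 kb (Btg2, Dusp1, Egr1, Fos, Fosb, Ier2, Jun, Junb, Jund, Klf2, Klf4 and Nr4a1). All 19 of these regions had a positive log2 fold change in the authors' deposited table and 0 had a negative one, and 1 of the 19, at Klf2, passed the adjusted threshold. The list was fixed before the data were examined, but the 5 kb assignment was chosen after seeing them. By this assignment 35.3% of the list's genes had a listed region against 2.01% of the other 19882 protein-coding genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 3.1e-11 over 17 lists). This comparison ignores how many tested regions lie near each gene, which is not known here, so a gene with many regions is favoured. By Fisher's exact test against genes with a region in any of the 3 lists the adjusted p was 0.00099, and the test of higher against lower regions did not pass (p = 0.042, adjusted p = 0.357). Under the annotation carried by the files, which attaches no gene to most intergenic regions, only Fosb and Nr4a1 counted, and the list did not pass.

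**Figure D1:**
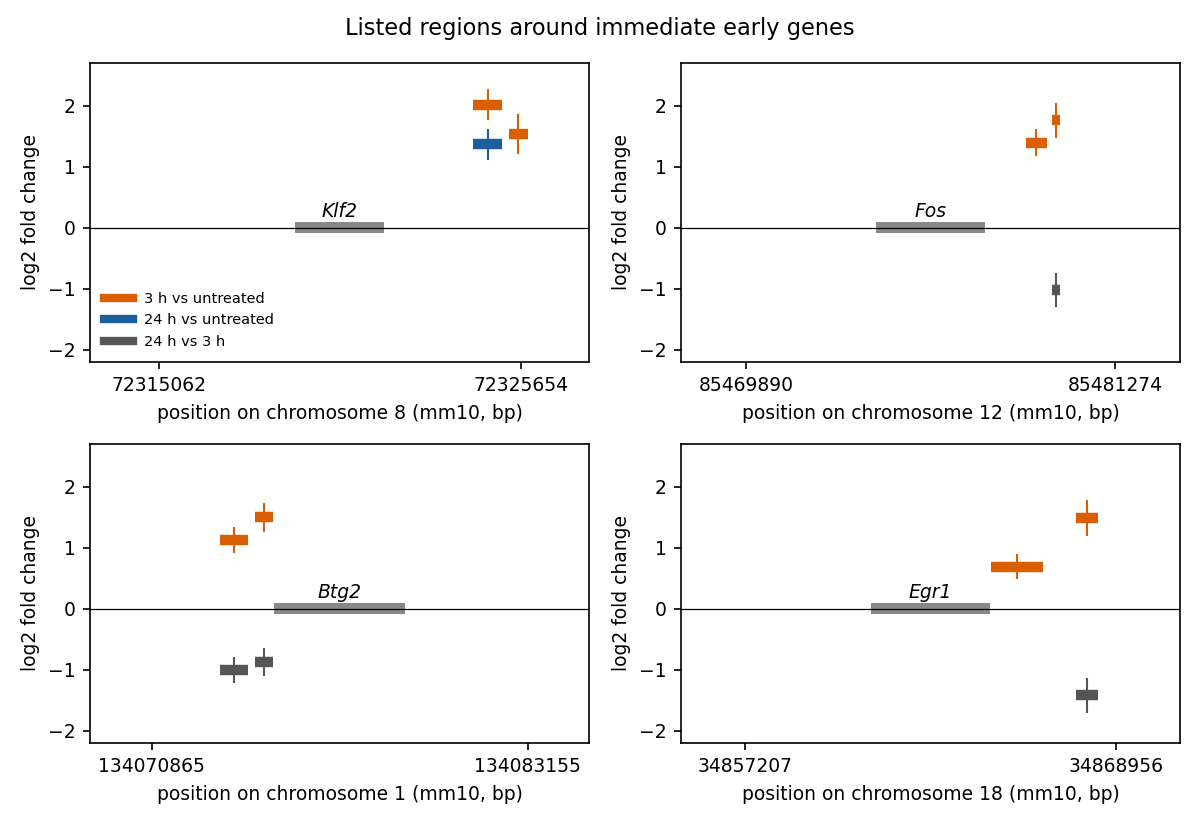
Listed regions around Klf2, Fos, Btg2 and Egr1 (gene bodies in grey; x axis, position on mm10 in bp; y axis, the authors' log2 fold change). Horizontal bars span each region, colours give the comparison, and vertical lines are 1 approximate standard error derived from the authors' F statistic. The 3 h regions lie outside the gene bodies with log2 fold changes from 0.69 at Egr1 to 2.02 at Klf2.

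Other genes named by the fixed rule at 3 h did not pass the adjusted threshold, and their values are given as listed. In the authors' deposited table the log2 fold change was 1.14 at the promoter of Rara, the retinoic acid receptor alpha gene, 1.11 near Cemip2, 0.90 at Gdpd5, 0.85 at Tppp3, 0.91 in Bcar1, 0.88 at Fzr1 and 0.95 in a Dyrk1a intron, with edgeR adjusted p from 0.338 to 0.383. The largest positive values at such genes in the authors' deposited table, besides Iqcn, were 1.90 in a Jade1 exon and 1.82 at Eml5 (edgeR adjusted p = 0.939 and 0.990). Both regions had a low mean log2 CPM (-0.66 and -0.56). Negative log2 fold changes in the authors' deposited table were -0.99 at Tgif1, a transcriptional repressor gene of the TGF-beta pathway, -0.88 at Ttc33, -0.89 at Rad51b, -0.85 at Arl6ip5, -0.80 at Fank1, -0.79 at Slco3a1, -0.82 at Iffo1 and -0.84 at Medag (edgeR adjusted p from 0.338 to 0.623). Values of -1.41 at Zdhhc14, -1.36 near Adh6-ps1 and -1.28 at Tll2 were the most negative at such genes in the authors' deposited table.

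Members of the other fixed lists were few at 3 h. Sarcomere genes gave 3 of 44 members, and the authors' deposited table had log2 fold changes of -1.27 at the promoter of Actc1, which encodes cardiac alpha-actin, and -0.66 in Myom1. The list for the ubiquitin-proteasome system, autophagy and atrophy gave 2 of 32, the protease genes Ctsl (1.20) and Capn2 (0.93) in the authors' deposited table. Myogenic regulators gave 2 of 39, Itga7 (0.64) and Hdac4 (-0.61), and TGF-beta and YAP genes gave 2 of 31, Amotl2 (0.65) and Ajuba (-0.59), in the authors' deposited table. With 1 member each, the authors' deposited table held Ass1 (0.85) for amino acid metabolism, Atf3 (1.21) for the integrated stress response, Rela (-0.61) for NF-kB, Irs1 (0.99) for insulin signalling, Ccnd2 (0.68) for the cell cycle, Atp2b1 (0.77) for ion transport and Postn (0.85) for fibroblast markers. Car9, of the hypoxia list, had both a higher and a lower region. The lists for mitochondrial metabolism, oxidative stress, myoblast and reserve cells, and adipocyte and smooth muscle cells had 0 members. None of the 17 lists passed in either Fisher's exact test with the files' annotation, and 0 had an unadjusted p below 0.05.

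Regions that were higher at 3 h lay at promoters and CpG-rich sequence far more often than regions that were lower. Promoters held 24.2% of the 327 higher regions (95% Clopper-Pearson interval 19.6 to 29.2) and 7.66% of the 261 lower ones (4.74 to 11.6; Fisher's exact test, two-sided, adjusted p = 1.6e-07). CpG islands held 28 higher regions and 1 lower region (adjusted p = 1.8e-06), and CpG shores 22.9% against 5.36% (adjusted p = 3.6e-09). Intergenic sequence held 26.0% of higher and 47.5% of lower regions (adjusted p = 1.6e-07). Benjamini-Hochberg adjustment covered 33 tests of 11 annotation classes in 3 comparisons. Regions in the flank of a gene with no upstream annotation, a class defined after seeing the data, made up 16.5% of higher and 1.53% of lower regions (Fisher's exact test, adjusted p = 3.8e-10).

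**Figure D2:**
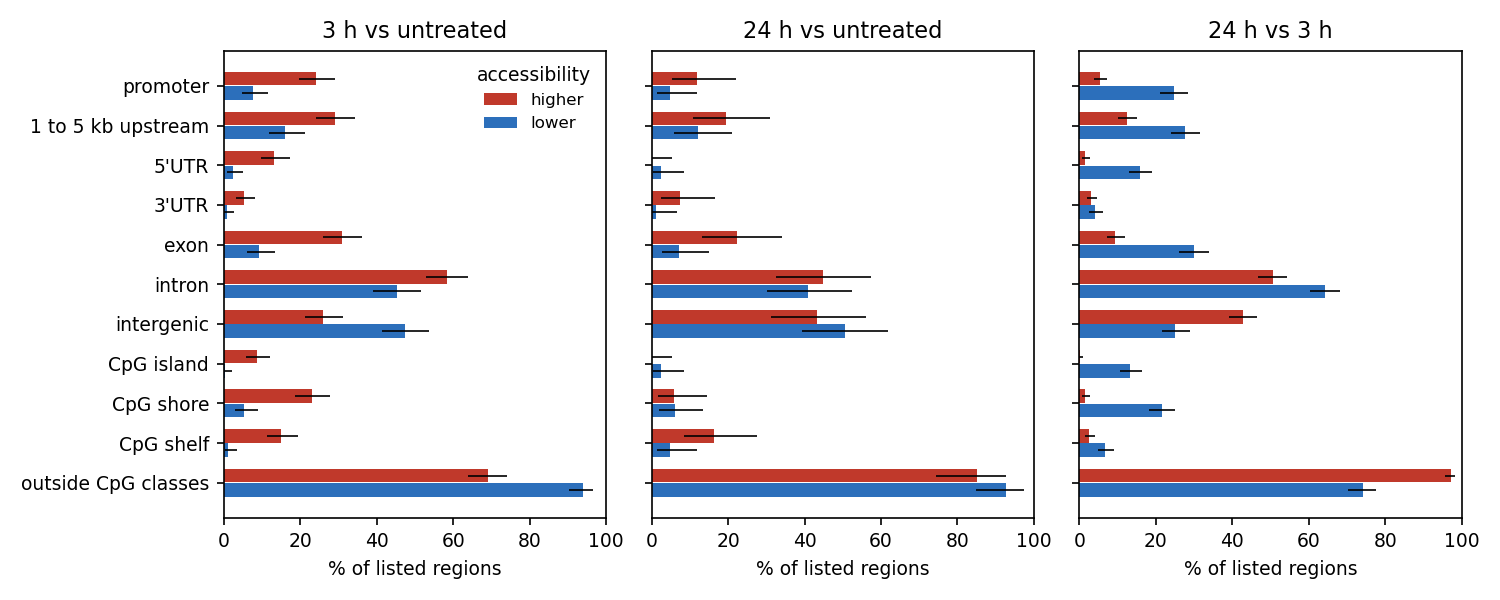
Share of listed regions in each annotation class (x axis, percent; bars, higher in red and lower in blue; lines, 95% Clopper-Pearson intervals) in the 3 comparisons. Promoters held 24.2% of higher and 7.66% of lower regions at 3 h, and 5.34% of higher and 24.7% of lower regions in 24 h against 3 h.

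At the largest p listed, 3 h against untreated gave no more regions than chance would. The 3 h list holds regions with raw p below 0.005 and at least a 1.5-fold change. The adjusted p values allow at most 729 of the 146047 tested regions at the largest p listed, where chance gives 729, both without the fold limit. The 588 listed regions, 55.6% of them higher (51.5 to 59.7), also passed the fold limit, so their number cannot be set directly against that chance figure. At the largest raw p of the 24 h list, 21 regions were listed at 3 h, 19 of them higher, where chance gives 7.49. The annotation tests describe the list and not single regions.

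After 24 h, 150 regions passed edgeR's test at an adjusted p below 0.05, where chance gives 7.49 at the same raw p. Accessibility rose at 67 and fell at 83 of them (44.7% higher, 95% Clopper-Pearson interval 36.6 to 53). The smallest p belonged to an intron of Plekha6 (chromosome 1, 133217458 to 133218192), where accessibility fell by 1.46 on the log2 scale (edgeR adjusted p = 0.00113 in the authors' deposited table). It also fell in introns of Cpa5 (log2 fold change -1.32), Ttc33 (-1.14), Rbfox3 (-1.12), Anxa6 (-0.94) and Sema5b (-1.23), in Fank1 (-1.08), and at the promoter of Arhgap22 (-1.34), in the authors' deposited table (edgeR adjusted p from 0.0077 to 0.0257). Regions that rose lay in introns of Fnip2 (1.09), which encodes a folliculin partner, Nrg1 (1.23), a growth factor gene, Lrig1 (1.16), Arhgap12 (1.07) and Nipa1 (1.05), and at Zcchc2 (1.35), Wdr33 (1.23), Csnk1d (1.48) and Masp1 (1.36), in the authors' deposited table (edgeR adjusted p from 0.0096 to 0.0298). The highest value at a named gene in the authors' deposited table was 2.64 in a Jade1 exon (edgeR adjusted p = 0.0421), a region with a low mean log2 CPM of -0.66.

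Of the fixed lists, 3 had 1 member each at 24 h. Accessibility rose in Rragc (log2 fold change 1.09), which encodes a Rag GTPase of the mTORC1 pathway, and fell in Dusp4 (-1.12), a MAP kinase phosphatase gene, and Ltbp1 (-0.84), a latent TGF-beta binding protein gene, in the authors' deposited table (edgeR adjusted p = 0.0499, 0.0444 and 0.0499). By the authors' annotation the remaining lists had 0 members, and no list passed. With the 5 kb assignment 6 lists had a member, and again none passed. Near genes chosen after their values were seen, accessibility rose at Neat1, a nuclear long noncoding RNA gene (2.82-fold at a region 2034 bp away, and log2 fold changes of 1.32 and 1.19 within the gene), at the Klf2 region described above (1.37), 1578 bp from the stress gene Ddit4 (0.99), and at Tnfaip2 (1.10), in the authors' deposited table (edgeR adjusted p from 0.0077 to 0.0469).

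The annotation of regions that rose and fell at 24 h differed less clearly. Exons held 22.4% of regions that rose and 7.23% of those that fell (Fisher's exact test, adjusted p = 0.0142), and CpG shelves 16.4% and 4.82% (adjusted p = 0.0386). Promoters held 11.9% and 4.82% (adjusted p = 0.179), which did not pass. When each region was given only its foremost class, the exon difference no longer passed (Fisher's exact test, p = 0.243).

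Between 3 h and 24 h, 0 of the 1256 listed regions had an edgeR adjusted p below 0.05, and 29 were below 0.25. All 1256 have a raw p below 0.005. The smallest p belonged to Hdac5, a class IIa histone deacetylase gene, with a log2 fold change of -1.04, followed by Col18a1 (-1.07) and Cpne8 (1.14), in the authors' deposited table (edgeR adjusted p = 0.195 for each). Positive values in the authors' deposited table were 1.08 at Nipa1, 1.22 at the promoter of the kinesin gene Kif5b, 0.95 in Ext1, 1.22 in Hs3st3a1, 0.99 in Cyp39a1 and 0.98 in Plekhm3, with edgeR adjusted p from 0.198 to 0.257. A Kifap3 intron was 2.01-fold higher in the authors' deposited table (edgeR adjusted p = 0.222). Negative values in the authors' deposited table were -0.97 in Plekha2, -0.94 in Gdpd5, -0.93 in Siva1, -0.91 in Cpa5, -0.87 in Plekha6 and -1.13 in Bcl2l11, a pro-apoptotic gene (edgeR adjusted p from 0.222 to 0.257). The Gdpd5 region is not the one given at 3 h. The extreme values at named genes in the authors' deposited table were 2.19 in Trpm3, 1.87 in Csnk1g3 and 1.85 near Atp12a, and -1.77 in Trp53inp1, -1.68 in Nr2e1 and -1.59 near Dnase2a. These were weakly covered regions, with a mean log2 CPM from -0.38 to 0.43 against a list median of 2.34 (edgeR adjusted p from 0.346 to 0.520).

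Myogenic regulators had 5 of 39 members listed in this comparison, with Eya4 (0.98), Tead4 (0.86), Hdac5 (-1.04) and Pax7 (-0.62) named by the rule in the authors' deposited table. Sarcomere genes had 3 of 44, and the Actc1 promoter region had a log2 fold change of 1.13 and Tnnt1 one of -0.71 in the authors' deposited table. Amino acid metabolism had 3 of 32, Ampd3 (0.79), Bckdhb (0.89) and Got1 (-0.99), and the hypoxia and glycolysis list had 2 of 26, Car9 (0.60) and Pkm (0.64), in the authors' deposited table. With 2 members each, the authors' deposited table held Rps6kb1 (1.20) and Tsc2 (-0.61) for mTORC1 signalling, Dusp4 (-0.77) and Fosb (-0.82) for immediate early genes, Ltbp1 (0.97) and Skil (-0.88) for TGF-beta, Atp2b4 (-0.76) and Kcnj12 (-0.66) for ion transport, Fn1 (0.74) and Twist2 (-0.93) for fibroblasts, and Dll1 (-0.65) and Pax7 for myoblasts. The Ltbp1 region is not the one that fell at 24 h, and the Car9 region is not among those listed at 3 h. No list passed, and 0 of the 17 had an unadjusted p below 0.05. With the 5 kb assignment, 8 immediate early genes (Btg2, Dusp4, Egr1, Fos, Fosb, Ier2, Jun and Junb) had a listed region, all with negative log2 fold changes. That was 23.5% of the list against 3.73% of other protein-coding genes (Fisher's exact test, adjusted p = 0.0005). As at 3 h, this background favours genes with many tested regions nearby. Against genes with a region in any list the list did not pass (Fisher's exact test, p = 0.564), nor did the direction test (adjusted p = 0.186).

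The annotation of this list mirrored the 3 h list. Promoters held 5.34% of the 693 higher regions and 24.7% of the 563 lower ones (Fisher's exact test, adjusted p = 2.5e-22). CpG islands held 1 higher and 75 lower regions (adjusted p = 2e-25), and intergenic sequence 42.7% and 25% (adjusted p = 1.8e-10). Both comparisons use the same 3 h libraries, so the mirror image is not independent of the 3 h result. The adjusted p values allow at most 1394 regions at the largest p listed, against 729 by chance.

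**Figure D3:**
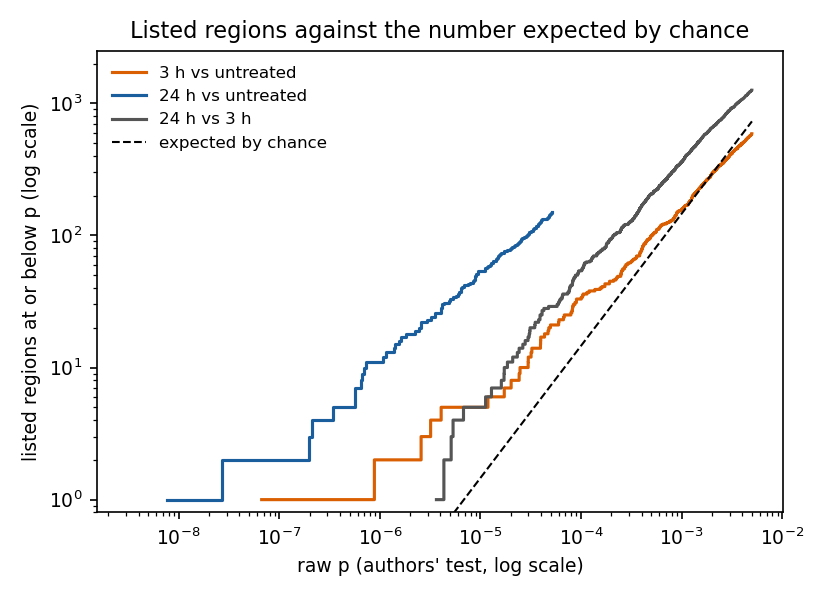
Number of listed regions at or below each raw p (both axes logarithmic) in the 3 comparisons, with the number expected by chance among 146047 tested regions as a dashed line. At the largest p of the 24 h list, 150 regions were listed for 24 h against untreated, 21 for 3 h against untreated and 29 for 24 h against 3 h, where chance gives 7.49.

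Many regions stood in more than 1 list. Of the 150 regions that changed at 24 h, 30 were also listed at 3 h, all in the same direction (20%, 95% Clopper-Pearson interval 13.9 to 27.3), among them the regions at Klf2, Ttc33, Fank1 and Jade1. In the list of 24 h against 3 h, 81 of the 150 appeared again in the same direction (54%, 45.7 to 62.2), among them Plekha6, Cpa5 and Nipa1. Of the 588 regions listed at 3 h, 54 were also listed in 24 h against 3 h, and 51 of those pointed the opposite way, including the regions at Egr1, Btg2 and Fos. Independent lists of these lengths would share 0.60, 1.29 and 5.06 regions. Libraries were simulated with no effect but with the shared groups, and their 24 h lists held 7.72 regions on average (2 to 19). They gave 40.3% (95% range 32.7 to 48.0) for the share of 24 h regions also listed at 3 h. The share also listed in 24 h against 3 h was 35.0% (27.3 to 42.7). Both ranges are for a list of the observed length. Opposite regions numbered 81.5 (62 to 106 over 100 runs). Part of each overlap may therefore come from shared libraries, and groups could not be split because the tables hold no values per library.

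**Figure D4:**
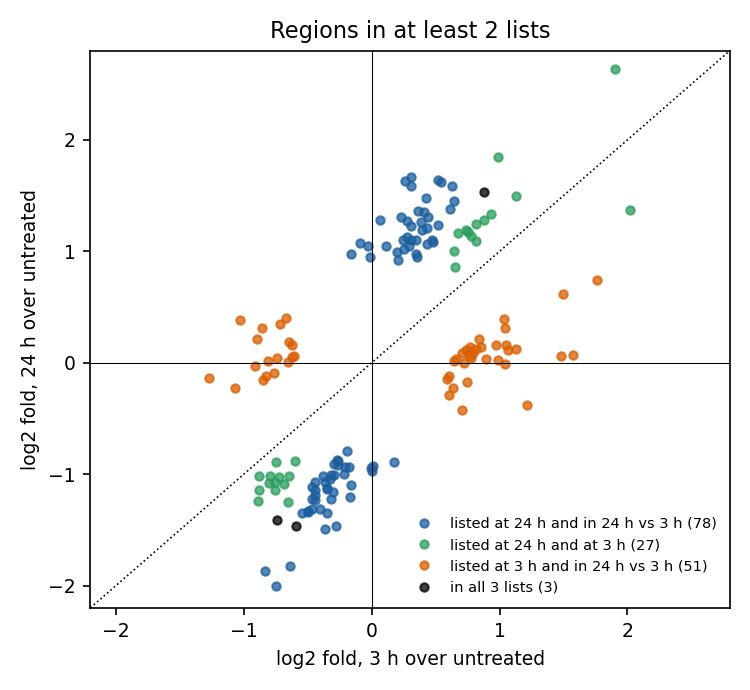
Log2 fold change over untreated at 3 h (x axis) and 24 h (y axis) for regions in at least 2 lists (points; colours give the lists; dotted line, equal values), where a missing value was derived from the other comparisons on the assumption that log2 fold changes add up, which could be checked in only 3 regions. The 78 regions listed at 24 h and in 24 h against 3 h lie near a 3 h value of 0.34 in their own direction. The 51 listed at 3 h and in the opposite direction in 24 h against 3 h have a median of 0.04 at 24 h in their 3 h direction, and single regions lie away from 0.

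In the 78 regions listed at 24 h and in 24 h against 3 h alone, the median derived change at 3 h was 0.34 on the log2 scale in the direction of the 24 h change (quartiles 0.24 and 0.44), against 1.13 at 24 h. In the 51 regions listed at 3 h and in the opposite direction in 24 h against 3 h, the median absolute change was 0.81 at 3 h. Their median derived value at 24 h in the 3 h direction was 0.04 (quartiles -0.13 and 0.12). Single regions differed from this median: the derived value at 24 h was 0.74 at Fos, 0.62 and 0.12 at Btg2, and 0.06 at Egr1. Selection into a pair of lists shapes these medians, and no correlation was computed for that reason. In the libraries simulated with no effect, 95.8% of 24 h regions found in another list had the same sign at 3 h, so a shared sign is not evidence of a change at 3 h.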

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

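The tests of the early gene folds and positions and of the overlaps between lists were chosen after the results were seen, and those of gene density and of well-covered regions before. Of the 150 regions that changed at 24 h, 81 were also listed in the same direction in the direct comparison of 24 h with 3 h, which drew attention to them as places where the time points may differ, although over all tested regions none of the 1256 regions of that comparison had an edgeR adjusted p below 0.05 (smallest 0.195; all 1256 have a raw p below 0.005). They include Plekha6, Cpa5 and Nipa1. With adjustment over the 150 regions alone, the largest adjusted p of the 81 was 0.00841, but the regions were chosen with the same 24 h libraries.

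Shared libraries are the technical explanation for all 3 overlaps, and it cannot be told apart from real changes for any of them. The 81 regions are 54% of the 24 h list, above the 42.7% at the upper end of the simulated range, but that simulation holds no effects while the 24 h list holds 150 regions where chance gives 7.49. The 20% of 24 h regions also listed at 3 h lies below the simulated 32.7 to 48.0%, but that range has the same limit, so it decides nothing. The 51 regions listed at 3 h and in the opposite direction in 24 h against 3 h lie below the simulated 62 to 106 (from lists without a fold limit). Their number alone therefore gives no evidence that early changes were transient. A response to ammonium acetate that grew between 3 h and 24 h stays open. So does a change with time in culture, since no time is given for the untreated group.

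Gains at CpG-rich promoters and losses away from them at 3 h, mirrored in 24 h against 3 h, were weighed next. A change limited to promoters is argued against, since outside promoters, upstream flanks and CpG classes the higher regions still had 9.01 genes per 500 kb and the lower ones 4.35 (permutation p = 2e-05, the smallest that 100000 resamples can give). Misjudged weak regions are argued against too, since above the median log2 CPM the promoter log2 odds ratio was 3.22. A broad trend of the 3 h libraries, such as a bias with base composition or in how open and closed chromatin were sampled, cannot be told apart from an effect of ammonium acetate at 3 h. Gene density outside those classes differed by -3.32 genes in 24 h against 3 h, but that comparison shares the 3 h libraries and would mirror either one, and no values per library could be compared.

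Regions beside immediate early genes at 3 h were the last pattern. The trend with CpG class and gene density is argued against as the whole cause: with these, promoters and log2 CPM adjusted for, and regions sharing a gene taken as 1 unit, the list's 12 units exceeded 233 other units by 0.41 on the log2 scale (permutation p times 17 lists = 0.00034). The large folds had been seen before this test. It replaced a first version without adjustment that had already been run on single regions (median difference 0.37, permutation p = 4e-05). Base composition itself was not measured, so a bias with it stays open. Whether these regions lay past the ends of genes more often than other higher regions near genes was not settled by the test used. Of the 15 regions outside gene bodies, 86.7% had no upstream annotation. That compares with 57.7% of the 71 other higher regions within 5 kb of a gene and outside gene bodies. With 1 region per unit the difference did not pass (Fisher's exact test, p = 0.069). An upstream label may belong to another transcript, so these shares do not measure position relative to the listed gene's own end. A response to ammonium acetate and an effect of handling the cultures at harvest both stay open, and neither was tested.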

How the results depend on the processing

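The limit of 1 raw p for all lists, the 5 kb assignment, the protein-coding background, the grouping of regions that share a gene and the thinning to 1 region per Mb were chosen after seeing the data. The counts of regions followed the threshold by construction. At an adjusted p of at most 0.01, 1 region (100% higher, absolute log2 fold change 2.02), 11 (63.6% higher, median 1.41) and 0 remained for 3 h, 24 h and 24 h against 3 h, with 0 shared between any pair of lists. At 1 raw p limit the counts were 21 (90.5% higher), 150 and 29 (65.5% higher). With an absolute log2 fold change of at least 1, 105 regions were listed at 3 h (72.4% higher) and 279 in 24 h against 3 h (69.2% higher). Above the median log2 CPM the counts were 294 (51.0% higher), 75 (34.7%) and 628, and the share of higher regions in the last reversed to 47.6%; the cause was not tested. By gene name, 17 and 44 were shared between the 24 h list and the 3 h and 24 h against 3 h lists. With 1 class per region (Fisher's exact test) the exon log2 odds ratio fell to 0.94 at 3 h (p = 0.086) and 1.52 at 24 h (p = 0.243). Among the 11 strictest 24 h regions the log2 odds ratio changed sign for promoters (1.34 to -2.68) and intergenic sequence (-0.42 to 2.36), none of these past Fisher's exact test, and exons and CpG islands held none of the 11, so they gave no value. The 5 kb assignment alone gave 1 list past the threshold at 3 h and 0 in 24 h against 3 h, and the 5 kb assignment and protein-coding background together gave 3 and 1, where the files' annotation and background gave 0. With 1 region per Mb, 0 and 1 chromosomes differed in direction at 3 h and in 24 h against 3 h, where 1 and 3 had. The other 39 planned and 9 added values kept their direction and side of the threshold, or, for counts, shares and medians, stayed within 1.5 times, the interval or 1 SD. No paired analysis was possible because the tables hold no columns per library, and for the same reason leaving out a replicate and other splits of the libraries were not run; nor were the motif alternatives, which need a genome. Unknown depth limits what can be said of weak regions.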

Other observations

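The tests of gene lists against all protein-coding genes and the chromosomes thinned to 1 region per Mb were chosen after the results were seen, and the genes in this part were chosen after their values were seen. At 3 h several genes had higher regions in or within 5 kb of them. H3f3b, a gene for histone H3.3, had 4 regions from 322 to 3399 bp away with log2 fold changes from 1.02 to 1.22 in the authors' deposited table, with edgeR adjusted p from 0.338 to 0.961. Vim, the vimentin gene, had a log2 fold change of 1.42, and regions 742 and 248 bp from Anxa1, annotated to introns of another transcript, had 1.67 and 1.03 in the authors' deposited table, none past the adjusted threshold. Atf3, a stress-induced transcription factor gene, had log2 fold changes of 1.15 in its 3' untranslated region and 1.21 in an intron, and 1.57 at a region 3585 bp away, in the authors' deposited table, and the last of these regions had a negative value in 24 h against 3 h.

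With the 5 kb assignment, 2 more lists passed at 3 h against all protein-coding genes, but neither passed against genes with a region in any list (Fisher's exact test, adjusted p = 0.254 for sarcomere genes and 0.594 for TGF-beta and YAP genes). Sarcomere genes had 5 of 44 members within 5 kb of a listed region (Actc1, Mybph, Myom1 and Tpm2 among them, with lower regions; Fisher's exact test against all protein-coding genes, adjusted p = 0.0116). TGF-beta and YAP genes had 5 of 31 (among them Amotl2 and Ccn1 with higher regions and Acta2 and Ajuba with lower ones; adjusted p = 0.0034). This background ignores how many tested regions lie near each gene, which the tables do not give, so a gene with many regions is favoured.

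With all listed regions, higher and lower ones were unevenly spread over a few chromosomes. At 3 h chromosome 8 held 29 higher and 7 lower regions (Fisher's exact test, adjusted p = 0.0332). In 24 h against 3 h, chromosomes 7 (21 higher, 38 lower), 8 (27 and 48) and 13 (47 and 16) passed, with adjusted p = 0.0192, 0.0144 and 0.0162. No chromosome passed at 24 h. With 1 region per Mb, 0 chromosomes passed at 3 h and 1 in 24 h against 3 h. Among the sizes of listed changes, higher regions had the larger median absolute log2 fold change in each comparison: 0.77 against 0.72 at 3 h (permutation p = 0.00054), 1.13 against 1.06 at 24 h (p = 0.028) and 0.84 against 0.76 in 24 h against 3 h (p = 2e-05, the smallest that 100000 resamples can give). The higher regions also had the smaller median log2 CPM in each comparison: 2.45 against 2.64 at 3 h, 2.69 against 3.15 at 24 h and 2.17 against 2.53 in 24 h against 3 h.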
